A study of Mus musculus with 20 samples.

How the data were processed

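Gene expression was measured on 20 Affymetrix mouse gene arrays, each from 1 pool of sorted mammary epithelial cells of mice on a mixed FVB/CD-1 background. Per the labels' protocols, cells were taken 4 weeks after tamoxifen from K8-creERT2 control mice and from K8-creERT2/PIK3CA H1047R mice. In the mutants, tamoxifen turns on a transgene for mutant PIK3CA, the catalytic subunit of PI3K, through a keratin 8-driven Cre, and GFP marks the cells that express it. Glands of 2 to 3 estrus-synchronized mice per genotype were pooled in each of 3 independent sortings, per the series design. CD45-negative cells were divided into a basal gate (CD24 low, Sca1 negative) and luminal gates (CD24 high, Sca1 negative or Sca1 positive). GFP-negative cells were collected from controls. GFP-positive cells were collected from mutants in all 3 gates, and GFP-negative cells in the basal gate. RNA of 2000 sorted cells was amplified before labelling, per the labels. Of the 7 groups, 6 had 3 arrays and the mutant Sca1-positive luminal group had 2, numbered 1 and 3. The number of arrays limits the precision of every value.

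The deposited values are log2 probe set summaries with 1 column per array. The unit was read from the values, which ran from 1.98 to 13.07 with none missing and with near-equal distributions on all arrays. The submitters' processing notes name the affy package without a version or a role. The normalization method, the filters and the genome build were not given in the sources used here, so no coordinates are printed. The deposited log2 values were used without further normalization, and replicates were not pooled.

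The value table held 34760 probe sets. Of these, 21640 were paired with a single gene symbol in the platform's table, 1321 with several symbols and 11799 were not listed there. Probe sets with several symbols or none were left out of the gene tests. Symbols were compared with a RefSeq mouse gene table (GRCm38.p6, used for names only), which held 21553 of the single-symbol probe sets by gene number and changed 0 symbols. Where a symbol had more than 1 probe set (954 genes), the probe set with the highest mean over all 20 arrays was used. This left 19937 genes, with no filter on intensity.

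All comparisons came from 1 linear model with 7 group means over the 20 arrays, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings). The spread within groups was thus estimated from all 7 groups together. It is the spread between separately sorted pools of mice, and the p-values measure differences against that spread. Gates and GFP fractions of the same genotype can come from the same pools, and this fit treats their arrays as independent. Of 14 contrasts, 5 were main comparisons: mutant against control in Sca1-negative luminal cells and in Sca1-positive luminal cells, GFP-positive and GFP-negative mutant basal cells each against control basal cells, and GFP-positive against GFP-negative basal cells of the mutants. A further 6 compared the lineages within controls and within GFP-positive mutant cells, and 3 were interactions, which test whether a lineage difference itself differed between mutants and controls. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, with no fold limit. The words rose and fell are used for called genes and lists. They name a difference between groups and not a change followed within cells. Overlaps between called sets were tested with Fisher's exact test (1-sided for enrichment) over the 19937 genes, between comparisons that share no arrays. These comparisons still share each gene's estimated spread and can share pools of mice. The expected counts and p assume that they are independent, so they can overstate the sharing.

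The gene lists were 26: basal myoepithelial, luminal general, luminal progenitor, hormone-sensing luminal, milk and secretion, FOXO-linked, PI3K pathway components, ERK pathway feedback, JAK-STAT feedback, cholesterol synthesis, fatty acid synthesis, glycolysis, ATF4 and amino acid response, ER chaperones, cell cycle, immediate early and stress, interferon response, Notch pathway, Wnt targets, EMT (epithelial-mesenchymal transition), immune cell, endothelial cell, fibroblast, pericyte, adipocyte and erythroid. They were written from textbook knowledge, and the basal, luminal and hormone-sensing lists hold markers of the sorted lineages. Members without a single-symbol probe set were not used here. The erythroid list kept 2 measured members. Each list was compared with all other genes by limma's camera at its preset correlation of 0.01, and p was adjusted over 130 tests (26 lists in 5 main comparisons). Camera was also run with the correlation between members estimated for each list. Members were counted as called over all genes and again with p adjusted over the list alone.

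A lineage score was the mean log2 level of genes higher in control basal cells minus that of genes higher in control luminal cells (called and at least 2-fold different). The signature came from control basal against Sca1-positive luminal cells for the Sca1-negative comparison, from control basal against Sca1-negative luminal cells for the Sca1-positive comparison, and from genes in both for the basal comparison. Scores were compared by an exact 2-sided permutation test, for which the smallest possible p was 0.1 with 3 arrays against 3 and with 2 against 3.

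Named genes followed a rule. In each main comparison these were the 12 genes with the highest and the 12 with the lowest log2 fold change among called genes whose compared arrays did not overlap. Predicted and unnamed gene models were skipped. Where fewer than 5 passed in a direction, the 5 with the smallest p were to be named. Up to 4 members of each list were named by size of change, called members first. In the lineage comparisons and interactions, 5 genes were named in each direction. Pik3ca, Krt8, Cd24a, Ly6a and Ptprc were named in every main comparison as driver, promoter gene and sort markers. Ly6a had no single-symbol probe set and was not used. Genes named outside the rule are stated to be so.

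The groups, contrasts, tests, lists, naming rule and alternative settings were fixed before the data were examined. The list tests on the interactions (78 tests) and the fit without the pair of arrays with a narrow spread of values were added after the data were seen. The alternatives set beforehand were fits of only the compared groups, eBayes with trend and robust settings, array weights, the replicate number as a fixed or a random block, a filter on dim genes, quantile normalization again, median centring, the mean of all probe sets of a gene, all probe sets tested, a 2-fold limit, each array left out in turn, other signatures for the score and the estimated correlation for the lists.

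The method was tested on simulated data in which 200 of 19937 genes were changed, 50 at each of 4 fold sizes. For the Sca1-negative luminal design, 40 of 50 genes changed 2-fold, 49 of 50 changed 4-fold, 48 of 50 changed 8-fold and 50 of 50 changed 16-fold were recovered, with 14 false calls among 201. For the Sca1-positive luminal design, 37 of 50 were recovered at 2-fold, 48 at 4-fold, 49 at 8-fold and 50 at 16-fold, with 11 false calls among 195. For GFP-positive basal against control, 44, 49, 50 and 50 of 50 were recovered at 2-, 4-, 8- and 16-fold, with 11 false calls among 204. For GFP-negative basal against control, the recovered numbers at the same sizes were 31, 49, 49 and 50 of 50, with 7 false calls among 186. For GFP-positive against GFP-negative basal, they were 39, 47, 50 and 50 of 50, with 13 false calls among 199. In a simulated shift of 0.7 on the log2 scale of the hormone-sensing list in the Sca1-negative luminal design, that list was called and 0 of the 25 unchanged lists were. The simulated noise was independent between genes and between arrays, and for each gene it had the same spread in all 7 groups. It therefore cannot show how often unchanged lists are called where their members correlate. Nor can it show how many genes are falsely called where groups differ in spread, as the basal arrays did. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.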

Results

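Expression was compared between 7 groups of sorted mouse mammary epithelial cells, 4 weeks after tamoxifen. Controls gave 3 arrays each of basal cells, Sca1-negative luminal cells and Sca1-positive luminal cells. PIK3CA H1047R mutants gave 3 arrays each of GFP-positive (transgene-expressing) basal cells, GFP-negative basal cells and GFP-positive Sca1-negative luminal cells, and 2 arrays of GFP-positive Sca1-positive luminal cells. Array medians lay between 3.66 and 3.80 on the log2 scale, and arrays of the same group correlated with r between 0.931 and 0.971 across probe sets. Replicate 2 of control Sca1-positive luminal cells and replicate 2 of mutant GFP-positive basal cells had a narrower spread of values (SD over probe sets 1.72 and 1.71) than the 18 other arrays (1.78 to 1.88).

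The main axis of variation separated basal from luminal cells. The first principal component (44.1% of variance) had group means of 49.5 in control basal, 45.3 in GFP-negative mutant basal and 40.8 in GFP-positive mutant basal cells. GFP-negative replicate 2 lay at 38.8, apart from the 2 others of its group (50.3 and 46.8) and among the GFP-positive arrays (38.5 to 42.1). The luminal means were -34.4 (control) and -26.4 (mutant) for Sca1-negative cells, and -43.6 (control) and -46.7 (mutant) for Sca1-positive cells. On the second component (12.03%), each GFP-positive mutant group lay below its control. The means were -24.1 against 17.9 in basal, -37.2 against 2.82 in Sca1-negative luminal and 5.85 against 25.6 in Sca1-positive luminal cells, while GFP-negative mutant basal cells had a mean of 11.1.

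**Figure D1:**
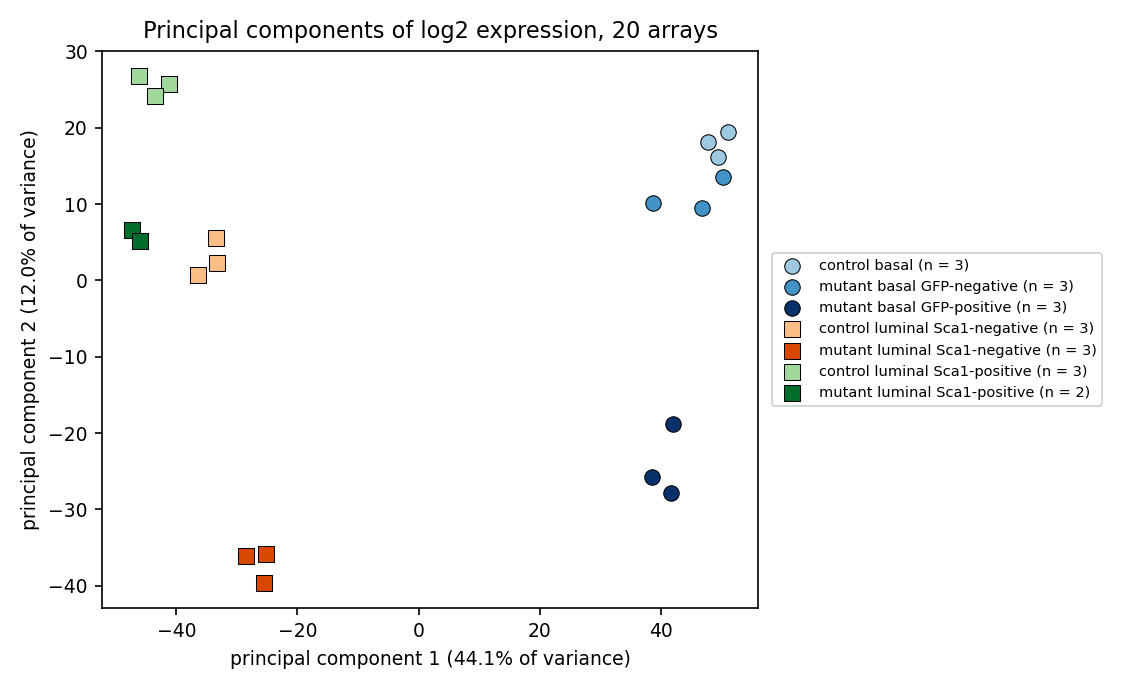
Principal components of log2 expression of 19937 genes on 20 arrays, with component 1 (44.1% of variance) on the x axis and component 2 (12.03%) on the y axis; each point is 1 array, circles are basal and squares luminal groups. Basal arrays lie to the right and luminal arrays to the left, and GFP-positive mutant arrays lie below the control arrays of their gate.

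The sort markers and the driver gene were examined as checks. Ptprc, which encodes CD45, had group means between 3.36 and 3.66 in every group, near the array medians. Krt8, whose promoter drives the Cre, had means of 11.88 to 11.96 in the luminal groups and 10.32 to 10.86 in the basal groups. Ptprc, Krt8, Cd24a and Pik3ca were not called in any of the 5 main comparisons. Whether the Pik3ca probe set detects the transgene was not tested, so its values do not measure transgene expression. For Pik3ca the log2 differences were 0.70 in Sca1-negative luminal cells (adjusted p = 0.279) and 1.04 in Sca1-positive luminal cells (adjusted p = 0.237). They were 0.04, -0.16 and 0.21 in the 3 basal comparisons (adjusted p = 0.965, 0.919 and 0.846).

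The first comparison asked what differs between Sca1-negative luminal cells that express mutant PIK3CA and control cells of that gate. Mutant luminal cells were collected as GFP-positive and control cells as GFP-negative. The luminal comparisons therefore do not separate the mutant from the choice of cells in which the Cre acted. The acute-phase serum amyloid genes were the most strongly raised. Saa1 had a mean log2 level of 10.22 ± 0.21 (SD, n = 3) in mutant and 3.10 ± 0.26 (SD, n = 3) in control cells, and Saa2 was higher by 6.42. Amtn (amelotin, an enamel matrix protein) rose by 5.75, the milk protein gene Wap by 4.85, the L-amino acid oxidase gene Lao1 by 3.15 and the chitinase-like gene Chil1 by 3.03. S100a8, a calcium-binding protein abundant in neutrophils, rose by 3.61 to 9.15 ± 0.52 (SD, n = 3). Wfdc3, the kallikrein gene Klk10, the endocytic adaptor gene Dab2, Elapor1 and the carbonic anhydrase gene Car2 rose by 2.93 to 3.02. In the other direction, the keratin gene Krt4 fell by 4.54 on the log2 scale, to 4.54 ± 0.05 (SD, n = 3) from 9.09 ± 0.51 (SD, n = 3).

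Genes of hormone-sensing luminal cells fell in the mutant Sca1-negative gate. Of the 10 measured members of that list, 6 fell and 4 were not called, and 8 fell when adjusted over the list alone. Pgr, the progesterone receptor gene, was at 4.95 ± 0.10 (SD, n = 3) in mutant and 7.59 ± 0.03 (SD, n = 3) in control cells. Prom1 fell by 2.29, Foxa1 (a pioneer factor for the estrogen receptor) by 2.11 and the T-box repressor gene Tbx3 by 1.58 on the log2 scale. The list's mean change was -1.35 (camera adjusted p = 5.83e-13, and adjusted p = 0.00135 with an estimated correlation). Outside the list, Tph1 (the rate-limiting enzyme of serotonin synthesis) fell by 4.02, the fibrinogen chain genes Fgb and Fgg by 3.73 and 3.36, R3hdml by 3.36, Rnf208 by 3.10 and Plac8 by 2.99 on the log2 scale. Dcn (the proteoglycan decorin), Upk3a, Krt6a and Gipc2 fell by 2.83, 2.80, 2.78 and 2.73.

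Milk and glycolysis genes rose in the same cells. Of 9 milk and secretion genes, Wap and Xdh (1.56, needed for milk fat secretion) rose and 7 were not called, while 6 rose when adjusted over the list alone. The list's mean change was 1.76 (camera adjusted p = 6.01e-06, and 0.0126 with an estimated correlation). The casein genes Csn2 and Csn1s2a differed by 3.17 and 3.14 but varied between control pools (adjusted p = 0.222 and 0.284). In the glycolysis list, 4 of 13 members rose and 9 were not called (5 rose adjusted over the list alone). These were Ldha by 1.46, Pfkp by 1.42, the glucose transporter gene Slc2a1 by 1.09 and Pkm by 0.80 (camera adjusted p = 2.7e-05, and 0.0495 with an estimated correlation).

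A further 6 lists were called in Sca1-negative luminal cells only with the preset correlation. In luminal progenitor genes (mean 0.45, adjusted p = 0.00405), the transcription factor gene Elf5 rose by 2.23 and 11 of 12 members were not called, with 2 higher adjusted over the list alone. The adjusted p was 0.162 with an estimated correlation. For fatty acid synthesis (mean 0.62, adjusted p = 0.000804), 0 of 11 members were called over all genes or adjusted over the list alone. For cholesterol synthesis (mean 0.26, adjusted p = 0.00272), 0 of 16 were called and 1 was higher adjusted over the list alone. With an estimated correlation the adjusted p was 0.135 for fatty acid and 0.166 for cholesterol synthesis. In the ATF4 and amino acid response (mean 0.37, adjusted p = 0.00184), the serine synthesis gene Psat1 rose by 1.25 and 15 of 16 were not called, with 4 higher adjusted over the list alone. In ER chaperones (mean 0.27, adjusted p = 0.00184), Sdf2l1 rose by 0.92 and 12 of 13 were not called, with 1 higher adjusted over the list alone. With an estimated correlation the adjusted p was 0.285 for the ATF4 list and 0.219 for ER chaperones. Of 15 immediate early and stress genes (mean -0.19, adjusted p = 0.045), Fos fell by 1.10, Klf4 by 0.99 and the heat-shock gene Hspa1a by 0.67 on the log2 scale, and 12 were not called. Adjusted over the list alone, 2 were higher and 7 lower, and the adjusted p was 0.544 with an estimated correlation.

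The other 17 lists were not called in Sca1-negative luminal cells (adjusted p from 0.181 for ERK pathway feedback to 0.923 for adipocyte). Single members rose in 3 of them, Cited2 in the FOXO-linked list by 1.27, Phlda1 in the ERK pathway feedback list by 0.63 and the matricellular protein gene Sparc in the EMT list by 2.32. Mean changes were 0.17 for basal myoepithelial, 0.10 for luminal general, 0.22 for FOXO-linked, 0.16 for ERK pathway feedback, 0.12 for Wnt targets, 0.14 for cell cycle, -0.11 for interferon response and -0.22 for JAK-STAT feedback genes, and 0.034 for PI3K pathway components. Markers of other cell types had mean changes of 0.035 (immune), -0.11 (endothelial), -0.21 (fibroblast, in which Dcn fell), -0.021 (pericyte), -0.016 (adipocyte) and -0.11 (erythroid). For the Notch, EMT and immune lists, the mean, the median and the direction of the test differed in sign.

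By limma, 378 of 19937 genes were called in Sca1-negative luminal cells, 242 higher and 136 lower, and 2235 had an unadjusted p under 0.05. The arrays of the groups did not overlap in 376 of the 378, which were called from the same arrays, and in 22.6% of all genes, against 10% by chance with 3 arrays against 3. The count was 819 with array weights, 249 without control replicate 1 and 248 without mutant replicate 3. Of the 41 named calls, 24 passed under every alternative set beforehand, and those of Lao1, Chil1, Klk10, Fgg, Upk3a, Krt6a, Elf5, Xdh, Slc2a1, Pkm, Psat1, Sdf2l1, Phlda1, Sparc, Fos, Klf4 and Hspa1a did not.

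The same question was put to Sca1-positive luminal cells, where 2 mutant arrays were set against 3 control arrays. Saa1 rose by 5.71 to 8.78 ± 0.14 (SD, n = 2) from 3.07 ± 0.60 (SD, n = 3), Saa2 by 4.38, Chil1 by 5.02, Wap by 4.27 and Amtn by 4.04. Slc28a3, a nucleoside transporter gene, rose by 3.12, Ceacam10 by 3.05, the cornified envelope gene Sprr2f by 3.03, Pwwp3b by 2.97, the dipeptidase gene Dpep2 by 2.70, Pate11 by 2.62 and the mucin gene Muc15 by 2.58. Fewer genes fell. They included Itih2 by 1.89, the intraflagellar transport gene Ift57 by 1.78, Krt4 by 1.72, the lysyl oxidase-like gene Loxl4 by 1.47, Chd9 by 0.95, Cdc42ep4 by 0.88, Ifitm3 by 0.79 and the glutamate receptor gene Grm8 by 0.72 on the log2 scale.

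Luminal progenitor, milk and glycolysis genes rose as groups in Sca1-positive luminal cells. Among 12 luminal progenitor genes, the siderophore-binding lipocalin gene Lcn2 rose by 1.83 and 11 were not called, while 7 rose when adjusted over the list alone. The mean change was 0.92 (camera adjusted p = 2.78e-08, and 0.0152 with an estimated correlation). Of 9 milk genes Wap rose, and 3 rose adjusted over the list alone (mean 1.803, adjusted p = 4.31e-05, and 0.0156 with an estimated correlation). In the glycolysis list, Tpi1 rose by 1.61 and Ldha by 1.18, 11 of 13 were not called, and 4 rose adjusted over the list alone (mean 0.47, adjusted p = 8.17e-06, and 0.0378 with an estimated correlation). Cholesterol synthesis (mean 0.45, adjusted p = 2.63e-06) and PI3K pathway components (mean 0.34, adjusted p = 0.00036) were also called, each with an adjusted p of 0.0378 with an estimated correlation. In these lists 0 of 16 and 0 of 14 members were called over all genes, and 3 and 2 were higher adjusted over the list alone.

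In 6 lists the call in Sca1-positive luminal cells was lost with an estimated correlation. Basal myoepithelial genes had a mean change of 0.45 (adjusted p = 3.53e-05, and 0.074 with an estimated correlation), with the basal keratin gene Krt5 higher by 2.14 as the 1 called of 17 by either adjustment. Luminal general genes had a mean of 0.33 with 0 of 13 called either way (adjusted p = 0.0104, and 0.391 with an estimated correlation). For FOXO-linked genes the mean was 0.42 with 0 of 14 called and 2 higher adjusted over the list alone (adjusted p = 0.000912, and 0.0833 with an estimated correlation). Fatty acid synthesis genes had a mean of 0.75 with 0 of 11 called and 2 higher adjusted over the list alone (adjusted p = 4.12e-05, and 0.0622 with an estimated correlation). ER chaperones had a mean of 0.30 (adjusted p = 0.000305, and 0.162 with an estimated correlation) and immediate early genes a mean of 0.32 (adjusted p = 0.000104, and 0.223 with an estimated correlation). In each of these, 0 members were called over all genes and 1 was higher adjusted over the list alone.

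Hormone-sensing genes were not called as a group in Sca1-positive luminal cells (mean -0.12, adjusted p = 0.375), with 0 of 10 called and 1 lower adjusted over the list alone. The other 14 lists that were not called had adjusted p from 0.136 (fibroblast) to 0.943 (cell cycle), and Sparc of the EMT list rose by 2.44. Mean changes of other cell types' markers were -0.023 (immune), -0.060 (endothelial), 0.22 (fibroblast), 0.015 (pericyte), -0.16 (adipocyte) and -0.14 (erythroid). Mean, median and test differed in sign for the ATF4, cell cycle, Notch, Wnt, EMT and fibroblast lists.

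By limma, 45 genes were called in Sca1-positive luminal cells, 36 higher and 9 lower, and 1786 had an unadjusted p under 0.05. In each of the 45, which were called from the same arrays, and in 28.6% of all genes, the arrays did not overlap, against 20% by chance with 2 arrays against 3. The count was 75 with array weights, 12 when only the 5 compared arrays were fitted and 19 without mutant replicate 3. Of 25 named calls, those of Amtn, Saa1 and Saa2 passed under every alternative set beforehand.

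The genes called in the luminal subsets overlapped. Both comparisons come from 1 fit and can share pools of mice, so the counts expected if independent can be too low. Of the 242 genes higher in Sca1-negative and the 36 higher in Sca1-positive luminal mutant cells, 16 were shared, against 0.437 expected if independent (Fisher's exact test, p = 7.93e-22). Of the 136 and 9 lower genes, 4 were shared, against 0.0614 expected (Fisher's exact test, p = 2.54e-07). Whether the difference between mutant and control cells itself differed between the luminal subsets was tested by the interaction, which called 28 genes, 22 with a more positive change in Sca1-positive cells and 6 with a more negative one. Tph1 (3.16), Plac8 (3.05), R3hdml (2.97) and Krt4 (2.82) had a more positive change in Sca1-positive cells, as did Pwwp3b (2.80), which rose there. Fyb2, Ogfrl1, Tmem37, Trpm6 and Smoc1 had interaction values of -2.29, -2.11, -1.67, -1.56 and -1.51. As a group, hormone-sensing genes differed between the subsets, with a mean interaction of 1.23 (camera adjusted p = 4.93e-09, and 0.00588 with an estimated correlation), although 0 of its 10 members were called alone and 6 were higher adjusted over the list alone. The count was 72 with array weights, 45 without control Sca1-positive replicate 1 and 46 without mutant Sca1-positive replicate 1. The calls of Krt4, Tmem37 and Tph1 passed under every alternative set beforehand, and those of the other 7 named genes did not.

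**Figure D2:**
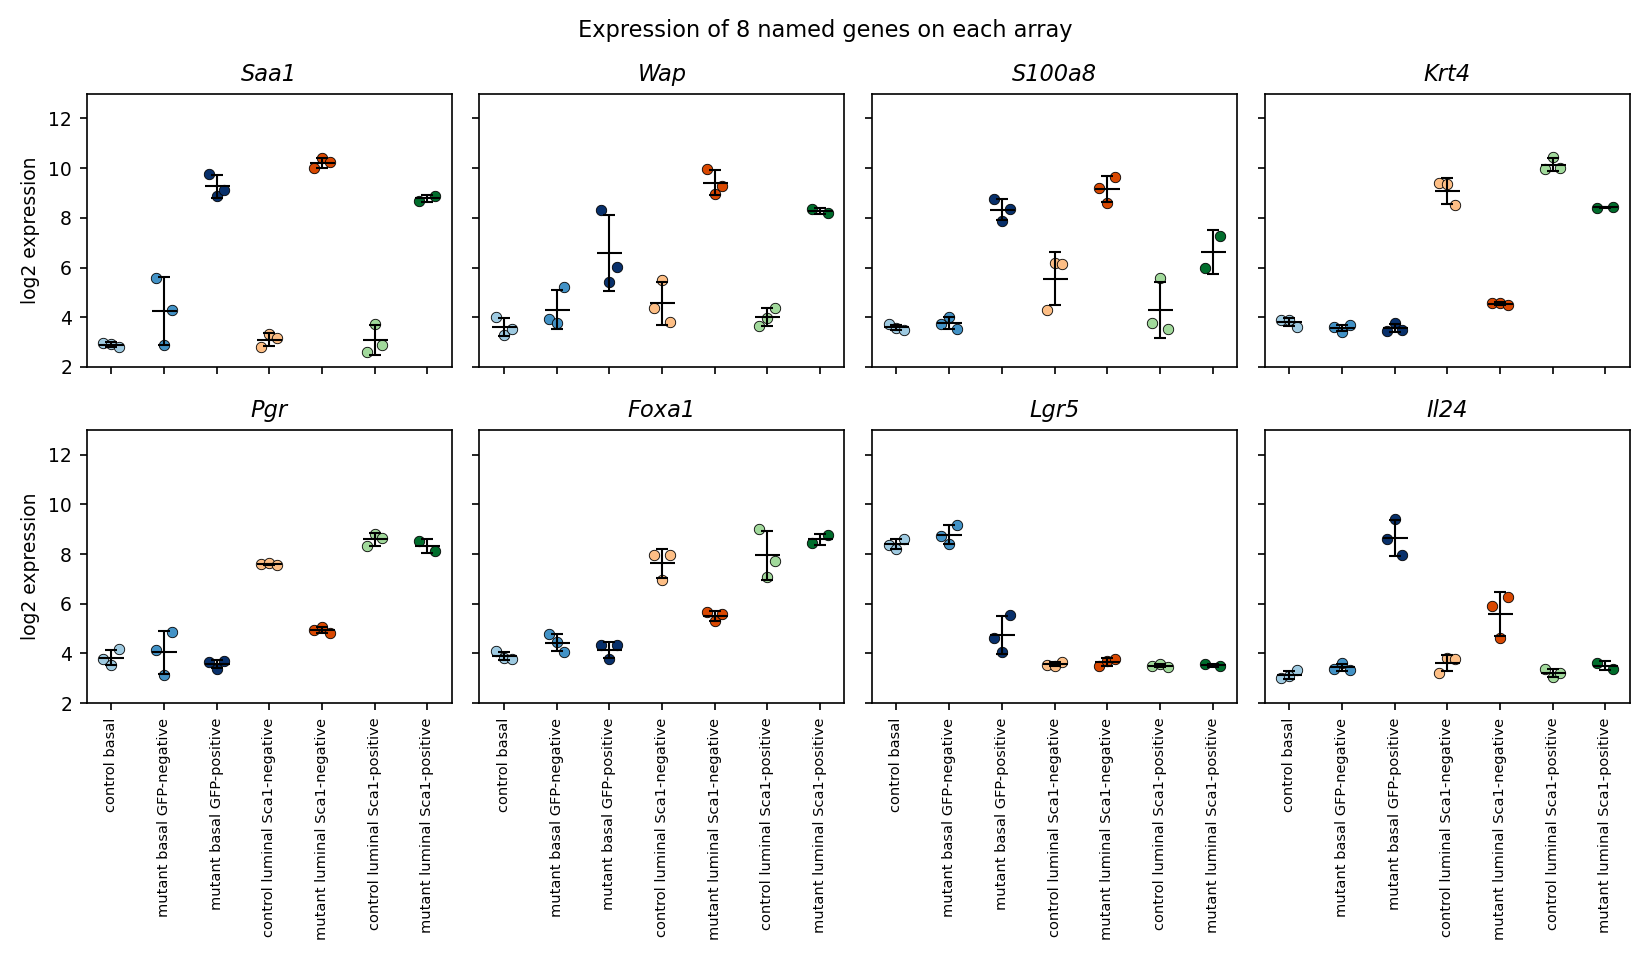
Log2 expression (y axis) of 8 named genes in the 7 groups (x axis); each point is 1 array, and bars show the mean and SD (n = 3, or 2 for mutant Sca1-positive luminal cells). Saa1 lies at 10.22 in mutant and 3.10 in control Sca1-negative luminal cells, and Lgr5 lies at 4.73 in GFP-positive, 8.77 in GFP-negative and 8.39 in control basal cells.

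The next comparison concerned transgene-expressing cells found in the basal gate, set against control basal cells. The Cre is driven by keratin 8, and whether control basal cells match the cells from which these arose was not tested. Saa1 rose by 6.37 to 9.26 ± 0.46 (SD, n = 3) from 2.89 ± 0.09 (SD, n = 3), and Saa2 by 5.14. Il24 (IL-10 family) rose by 5.51, the alarmin gene Il33 by 4.12, Scrg1 by 5.49, Fndc1 by 4.997 and the matricellular protein gene Sparcl1 by 4.92. S100a8 rose by 4.74, the carbonic anhydrase gene Car12 by 4.62 and the thioesterase gene Them5 by 4.50. Among the genes that fell, Lgr5, a receptor for the Wnt amplifier R-spondin, was at 4.73 ± 0.76 (SD, n = 3) in GFP-positive and 8.39 ± 0.20 (SD, n = 3) in control basal cells. The glutamate receptor gene Grik3 fell by 4.64, the sodium channel gene Scn7a by 4.34, the microtubule protein gene Map1b by 3.42, Itprid1 by 3.33, Tfb2m by 3.18 and the mannosidase gene Man1a by 3.12 on the log2 scale. Cacna2d1, the complement inhibitor gene Serping1, Ankrd1, Tshz2 and Npw fell by 3.09, 3.03, 2.87, 2.85 and 2.83.

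Luminal progenitor and milk genes rose in these basal-gate cells. Of 12 luminal progenitor genes, 5 rose and 7 were not called, and 9 rose when adjusted over the list alone. Wfdc18 rose by 2.85, the transferrin gene Trf by 2.36, Mfge8 by 2.30 and Cd14 by 2.02 (list mean 1.33, camera adjusted p = 1.58e-10, and 0.0119 with an estimated correlation). Of 9 milk genes, 4 rose, 1 fell and 4 were not called, and 5 rose and 1 fell adjusted over the list alone (mean 1.57, adjusted p = 0.000721, and 0.0378 with an estimated correlation). The casein genes Csn2 and Csn1s1 rose by 5.18 and 4.61 and Wap by 2.98, while Glycam1 fell by 4.28 from a control mean with a large spread (7.53 ± 3.75, SD, n = 3). Luminal general genes were called with the preset correlation (mean 0.71, adjusted p = 0.000305), and the adjusted p was 0.214 with an estimated correlation. Of 13, 5 rose and 8 were not called (5 adjusted over the list alone), among them the ETS factor gene Ehf by 3.62 and the luminal keratin genes Krt7 by 1.80 and Krt19 by 1.48, and Cldn7 by 1.46.

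Other lists moved in GFP-positive basal cells with the preset correlation only. Of 10 Wnt targets (mean -0.82, adjusted p = 7.34e-05, and 0.0833 with an estimated correlation), Lgr5 and Lgr6 fell, by 3.66 and 1.38 on the log2 scale, and 3 fell adjusted over the list alone. Of 15 immediate early and stress genes (mean -0.53, adjusted p = 8.17e-06, and 0.162 with an estimated correlation), 4 fell and 9 fell adjusted over the list alone. These were Egr2, Hspa1a, Atf3 and Junb, by 1.39, 1.10, 0.70 and 0.60. In JAK-STAT feedback (mean -0.92, adjusted p = 0.0441, and 0.251 with an estimated correlation), Cish fell by 1.10, 3 of 4 were not called, and 2 fell adjusted over the list alone. Of 11 fatty acid synthesis genes (mean 0.87, adjusted p = 0.000305, and 0.0983 with an estimated correlation), the malic enzyme gene Me1 rose by 2.15, Elovl6 by 1.85 and Scd2 by 1.801, with 4 higher adjusted over the list alone. Of 16 cholesterol synthesis genes (mean 0.44, adjusted p = 0.00264, and 0.166 with an estimated correlation), Sqle and Sc5d rose by 1.76 and 1.21, with 3 higher and 1 lower adjusted over the list alone. ER chaperones had 0 of 13 called and 3 higher adjusted over the list alone (mean 0.36, adjusted p = 0.000305, and 0.162 with an estimated correlation). Of 12 endothelial markers (mean -0.39, adjusted p = 0.00114, and 0.285 with an estimated correlation), Cdh5 fell by 0.99 to 3.38, and 2 fell adjusted over the list alone.

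In the 16 lists not called in this comparison (adjusted p from 0.0709 for basal myoepithelial to 0.905 for FOXO-linked), single members moved both ways. In the basal myoepithelial list, 1 of 17 rose and 4 fell by either adjustment, with Lmod1 lower by 1.85, the oxytocin receptor gene Oxtr by 1.84 and P-cadherin (Cdh3) by 1.09, and Snai2 higher by 1.52. In the EMT list, N-cadherin (Cdh2) rose by 2.68 and Zeb1 by 0.71, while Fn1 fell by 0.57. In the FOXO-linked list, Sesn3 rose by 2.81, Bcl6 by 1.72 and Cited2 by 1.23, while the receptor gene Igf1r fell by 2.22, and among PI3K pathway components Irs1 fell by 1.61 and Inpp4b rose by 0.57. The Notch list had Jag1 higher by 2.41, Notch1 by 1.63 and Hes1 by 0.69. Tbx3 and Tnfsf11 of the hormone-sensing list fell by 2.45 and 0.37, and Phlda1 and Pfkp rose by 1.13 and 0.95. Mean changes of other cell types' markers were -0.10 (immune), 0.27 (fibroblast, with Dcn higher by 3.15 and Col1a2 by 0.88), -0.094 (pericyte, with Cspg4 higher by 0.72), -0.13 (adipocyte) and -0.21 (erythroid). For the FOXO-linked, PI3K, ERK, Notch, EMT and fibroblast lists, the mean, the median and the direction of the test differed in sign.

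By limma, 843 genes were called between GFP-positive mutant basal and control basal cells, 463 higher and 380 lower, and 3187 had an unadjusted p under 0.05. The arrays did not overlap in 834 of them and in 18.6% of all genes (10% by chance). The count was 276 when only the 6 compared arrays were fitted, and without GFP-positive replicate 2 it was 478 higher and 248 lower. Of 69 named calls, 36 passed under every alternative set beforehand, among them those of Saa1, Saa2, Il24, Il33, Scrg1, Csn1s1, Lgr5, Grik3, Ehf, Mfge8, Cdh2, Jag1 and Igf1r, while those of Csn2, Wap, Glycam1, Krt7, Krt19, Cldn7, Wfdc18, Trf, Cd14, Oxtr, Cdh3, Dcn, Lgr6 and 20 others did not.

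GFP-negative basal cells of the same mutants were compared with control basal cells to see what differs in cells without the transgene. The mechanosensitive channel gene Piezo1 rose by 2.01 to 7.74 ± 0.41 (SD, n = 3) from 5.72 ± 0.73 (SD, n = 3), and Me1 rose by 1.99, Thy1 by 1.63, the keratin gene Krt15 by 1.52 and the Notch effector gene Hes1 by 1.09. Cast, Ism1, Afdn, Dchs1, Gtf2ird1, Rpap2 and Tesk2 rose by 1.002 to 1.48. Zfp296 fell by 1.87, Arsb by 1.61, Serpinb11 by 1.49, Sncg by 1.35, Xkr4 by 1.26, Immp1l by 1.15 and the intermediate filament gene Synm by 1.08 on the log2 scale. Snx5, Cox10, Micu2, Pyy and S100b fell by 0.997, 0.91, 0.90, 0.86 and 0.58. Saa1 and Saa2 were higher by 1.35 and 1.19 without being called (adjusted p = 0.331 and 0.292), and Lgr5, Il24 and Scrg1 were not among the called genes.

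Of the 26 lists, the immediate early and stress list was called (mean -0.17, adjusted p = 0.0215, and 0.492 with an estimated correlation), with 0 of 15 members called by either adjustment. The other 25 lists had adjusted p from 0.0721 (cell cycle, mean -0.18) to 0.993 (glycolysis), with luminal progenitor at 0.103 and milk at 0.287. Mean changes of other cell types' markers were -0.075 (immune), -0.15 (endothelial), 0.19 (fibroblast, in which Thy1 rose), -0.056 (pericyte), 0.14 (adipocyte) and -0.069 (erythroid). Mean, median and test differed in sign for the basal myoepithelial, PI3K, fatty acid, glycolysis, ER chaperone, interferon and fibroblast lists.

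By limma, 32 genes were called in GFP-negative basal cells, 19 higher and 13 lower, and 1932 had an unadjusted p under 0.05. In each of the 32, and in 13.7% of all genes, the arrays did not overlap (10% by chance). The count was 0 when only the 6 compared arrays were fitted with limma (1362 at an unadjusted p under 0.05), 10 with array weights and 63 without GFP-negative replicate 3, and none of the 24 named calls passed under every alternative set beforehand.

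Within the mutants, GFP-positive basal cells were compared with GFP-negative basal cells of the same genotype. Il24 was at 8.65 ± 0.72 (SD, n = 3) in GFP-positive and 3.44 ± 0.15 (SD, n = 3) in GFP-negative cells. Saa1 rose by 5.02, Scrg1 by 4.93, Fndc1 by 4.88, Sparcl1 by 4.76, S100a8 by 4.57, Car12 by 4.18, the haptoglobin gene Hp by 4.11, Saa2 by 3.95, the proteoglycan gene Vcan by 3.78 and Il33 by 3.74. Grik3 fell by 4.76 and Lgr5 by 4.03 on the log2 scale, Lgr5 from 8.77 ± 0.38 (SD, n = 3). Scn7a, Map1b, Cacna2d1, Tnfsf9 and Vsnl1 fell by 4.00, 3.78, 3.62, 3.55 and 3.27, and Ankrd1, Prelp, the metalloproteinase gene Pappa, Dpysl2 and Serping1 by 2.81, 2.81, 2.80, 2.70 and 2.66.

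The luminal progenitor list again rose, with 4 of 12 members higher, 8 not called and 9 higher adjusted over the list alone. Trf rose by 2.29, Wfdc18 by 2.17, Elf5 by 1.94 and Mfge8 by 1.91 (list mean 1.16, camera adjusted p = 2.86e-08, and 0.0152 with an estimated correlation). In 9 further lists the call was lost with an estimated correlation. Of 9 milk genes (mean 1.54, adjusted p = 0.00264, and 0.0622 with an estimated correlation), Csn1s2a and Xdh rose by 4.62 and 1.85, with 5 higher adjusted over the list alone. Of 13 luminal general genes (mean 0.44, adjusted p = 0.0172, and 0.402 with an estimated correlation), Cldn7, Krt7 and Krt18 rose by 1.86, 1.36 and 1.06, with 5 higher and 1 lower adjusted over the list alone. Of 17 basal myoepithelial genes (mean -0.31, adjusted p = 0.0215, and 0.318 with an estimated correlation), Lmod1, Cdh3 and the smooth muscle myosin gene Myh11 fell by 2.26, 1.29 and 0.66, Snai2 rose by 1.41, and 1 was higher and 4 lower adjusted over the list alone. Of 10 hormone-sensing genes (mean -0.43, adjusted p = 0.0188, and 0.162 with an estimated correlation), Tbx3 fell by 2.07 as the 1 called by either adjustment. Of 10 Wnt targets (mean -0.72, adjusted p = 0.000721, and 0.155 with an estimated correlation), Lgr5, the feedback inhibitor gene Nkd1 (1.16) and Axin2 (0.91) were the 3 that fell, with 4 lower adjusted over the list alone.

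Metabolic and stress lists were also among these. Of 11 fatty acid synthesis genes (mean 0.79, adjusted p = 0.00222, and 0.162 with an estimated correlation), Scd2, Elovl6 and Thrsp rose by 2.35, 2.35 and 1.59, the 3 called by either adjustment. Of 13 ER chaperones (mean 0.29, adjusted p = 0.00158, and 0.214 with an estimated correlation), Manf and Hsp90b1 rose by 0.70 and 0.51, with 3 higher adjusted over the list alone. Of 15 immediate early genes (mean -0.36, adjusted p = 0.00145, and 0.324 with an estimated correlation), Egr2, Hspa1a and Atf3 fell by 1.45, 0.70 and 0.47, with 1 higher and 4 lower adjusted over the list alone. Of 4 JAK-STAT feedback genes (mean -0.72, adjusted p = 0.0437, and 0.251 with an estimated correlation), 0 were called and 2 were lower adjusted over the list alone.

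In the 16 lists not called between GFP-positive and GFP-negative cells (adjusted p from 0.052 for endothelial to 0.943 for pericyte), Cdh2, Snai2 and Zeb1 of the EMT list rose by 2.75, 1.41 and 1.16 and Fn1 fell by 0.65. Sesn3, Cited2, Jag1, Inpp4b and Phlda1 rose by 2.94, 0.90, 1.81, 0.53 and 1.26, and Igf1r and Irs2 fell by 2.29 and 0.96. Mean changes of other cell types' markers were -0.027 (immune), -0.24 (endothelial, with Plvap lower by 0.65), 0.079 (fibroblast, with Dcn and Col1a2 higher by 2.54 and 0.92 and Thy1 lower by 1.35), -0.039 (pericyte), -0.27 (adipocyte) and -0.15 (erythroid). Mean, median and test differed in sign for the PI3K, interferon, Notch, EMT, fibroblast and pericyte lists.

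By limma, 648 genes were called between GFP-positive and GFP-negative basal cells, 409 higher and 239 lower, and 2687 had an unadjusted p under 0.05. The arrays did not overlap in 630 of them and in 14.99% of all genes (10% by chance). The count was 134 when only the 6 compared arrays were fitted, and without GFP-positive replicate 2 it was 408 higher and 150 lower. Of 61 named calls, 31 passed under every alternative set beforehand, among them those of Saa1, Il24, Il33, Hp, Vcan, Lgr5, Grik3, Cldn7, Mfge8, Wfdc18 and Cdh2, while those of Saa2, Csn1s2a, Xdh, Trf, Elf5, Krt7, Krt18, Tbx3, Snai2, Zeb1, Axin2, Nkd1 and 18 others did not.

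**Figure D3:**
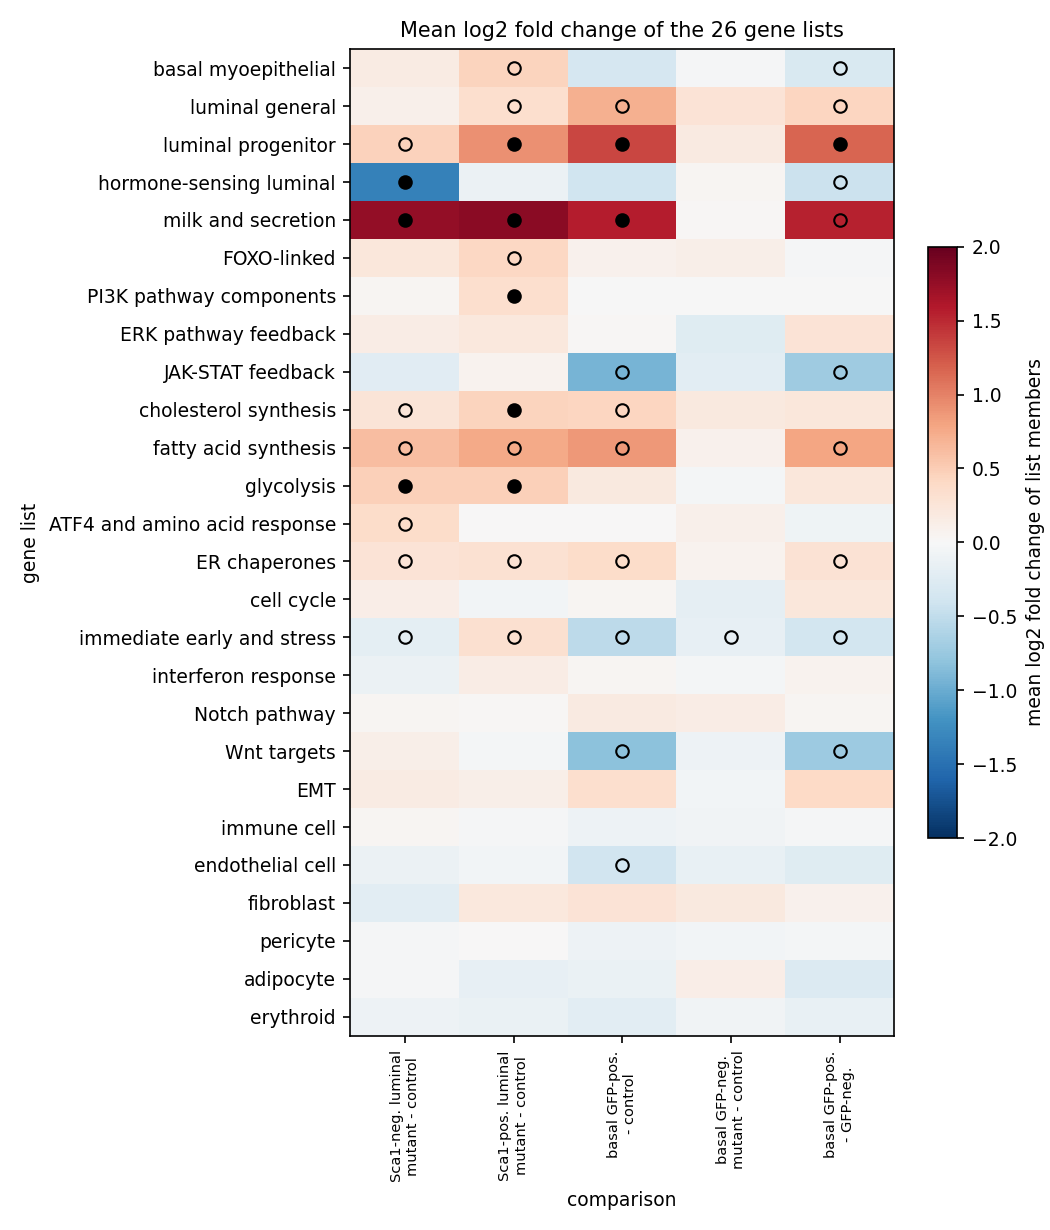
Mean log2 fold change (colour) of the measured members of the 26 gene lists (y axis) in the 5 main comparisons (x axis); an open circle marks a list called by camera with the preset correlation and a filled circle one also called with an estimated correlation. Milk genes are called higher at both correlations in the 3 comparisons of GFP-positive cells with control cells, luminal progenitor genes in 2 of them and in Sca1-negative luminal cells with the preset correlation only, and hormone-sensing genes reach -1.35 in Sca1-negative luminal cells.

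Genes higher with the transgene were compared across subsets in comparisons that share no arrays. They share each gene's estimated spread and can share pools of mice, so the counts expected if independent can be too low. Of the 242 genes higher in Sca1-negative luminal mutant cells, 45 were among the 409 higher in GFP-positive than GFP-negative basal cells, against 4.96 expected if independent (Fisher's exact test, p = 5.23e-30). For lower genes 14 of 136 were shared, against 1.63 expected (Fisher's exact test, p = 1.01e-09). Of the 36 genes higher in Sca1-positive luminal mutant cells, 11 were among the same 409, against 0.739 expected (Fisher's exact test, p = 8.98e-11), and of the 9 lower genes 0 were shared, against 0.108 expected. Common to all 3 were 10 higher genes, against 0.00896 expected if independent, and 0 lower genes. These 10 included Saa1, Saa2, Slc28a3, Ceacam10 and Muc15. The other 5 are named after their values were seen, and are Igfbp3 (higher by 2.55, 2.39 and 1.77 in Sca1-negative luminal, Sca1-positive luminal and GFP-positive against GFP-negative basal cells), Lrg1 (1.90, 2.11 and 1.61), Rb1 (1.45, 1.13 and 0.83), Sat1 (1.30, 1.49 and 1.12) and the choline kinase gene Chka (0.88, 0.92 and 0.55). In GFP-negative mutant basal cells against controls, all 10 were uncalled, with limma adjusted p from 0.206 to 0.999. This says little, as 0.161% of all genes were called there. The 10 genes were also chosen partly as lower in these GFP-negative arrays than in GFP-positive ones. Saa1 and Saa2 were higher by 1.35 and 1.19 in the GFP-negative cells.

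Lineage differences were compared between controls and GFP-positive mutant cells. Control basal cells differed from control Sca1-negative luminal cells in 1972 genes (931 higher in basal, 1041 lower), with the myosin genes Myl9 (11.31 ± 0.06 against 4.21 ± 0.37, SD, n = 3 each) and Myh11 on the basal side and Gpx3, the lactoferrin gene Ltf and Krt4 on the luminal side. The mutant contrast called 1911 genes (883 and 1028). Of the 1972, 935 were also called in the same direction in the mutants and 12 in the opposite direction. The interaction called 310 genes (187 with a more positive and 123 with a more negative difference in the mutants), 174 of them among the 1972. For basal against Sca1-positive luminal cells, 2445 genes were called in controls (1185 and 1260) and 2125 in mutants (896 and 1229), with 1163 in the same and 7 in the opposite direction. The interaction called 218, of which 122 were among the 2445. Quantile normalization again turned the balance of directions in both control contrasts (1064 higher and 957 lower, and 1321 and 1226) and in the mutant contrast with Sca1-negative luminal cells (995 and 807, and 863 and 699 without GFP-positive replicate 2). Without mutant Sca1-positive replicate 1 or 3, the mutant count of 2125 was 1341 and 1322, and without replicate 3 the interaction count was 117. That count was 124 when only the compared arrays were fitted.

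The interactions named genes that moved in basal-gate cells or in luminal cells. Against Sca1-negative luminal cells the highest interaction values were 5.97 for Dcn, 5.81 for Il33, 5.42 for Scrg1, 4.98 for Fndc1 and 4.31 for Krt4, which fell in the luminal cells. The lowest were -4.79 for Amtn, -4.34 for Scn7a, -4.25 for Grik3, -3.95 for Ptprz1 and -3.74 for Lgr5. Against Sca1-positive luminal cells, the values were 5.40 for Scrg1, 5.22 for Il24, 5.08 for Fndc1, 4.63 for Sparcl1 and 4.39 for Car12, and -4.62 for Grik3, -4.24 for Scn7a, -4.14 for Chil1, -4.03 for Man1a and -3.68 for Lgr5. All of these were called by limma, and that of Chil1 did not pass under every alternative set beforehand. As a group, Wnt targets changed more negatively in basal cells than in Sca1-negative luminal cells (mean -0.94, camera adjusted p = 1.64e-05) and than in Sca1-positive luminal cells (mean -0.78, adjusted p = 0.000381). With an estimated correlation the adjusted p were 0.0945 and 0.159.

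The Sca1-positive and Sca1-negative luminal subsets differed in 152 genes in controls (37 higher and 115 lower in Sca1-positive cells). Ltf was lower by 3.12, Chil1 by 3.33, Muc15 by 3.09, the matricellular protein gene Thbs1 by 3.05 and Igfbp5 by 3.04 in Sca1-positive cells, and Ccdc68, Ecscr, Trim29, Ift57 and Loxl4 were higher by 1.64, 1.61, 1.45, 1.36 and 1.33. In the mutants 813 genes differed (469 and 344), with Defb1, Ido1, Krt4, Plac8 and Tph1 higher by 4.14, 3.99, 3.88, 3.83 and 3.67 in Sca1-positive cells and Car2, Slc1a1, Gjb2, Lipa and Mgll lower by 3.05, 2.87, 2.85, 2.84 and 2.82. Of the 152 control differences, 111 were called in the same direction in the mutants and 0 in the opposite direction. Although 702 genes were called in the mutants and not in controls, the interaction called 28. The control count was 43 when only the compared arrays were fitted, 231 with array weights, 82 without control Sca1-negative replicate 1 and 83 without its replicate 3. The mutant count was 1493 with array weights, 460 without mutant Sca1-positive replicate 1 and 390 without replicate 3. Of the named calls, those of Ltf, Thbs1, Igfbp5 and Ecscr in controls and of Ido1, Krt4, Plac8, Tph1, Car2 and Slc1a1 in mutants passed under every alternative set beforehand, and those of the other 6 and 4 did not.

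The lineage score placed cells between basal and luminal profiles. Mutant Sca1-negative luminal cells scored -1.08 ± 0.06 (SD, n = 3) and controls -1.60 ± 0.07 (SD, n = 3), a difference of 0.52 against a control basal to luminal gap of 3.34 (exact 2-sided permutation p = 0.1, the smallest possible), and of 1.04 with a signature of genes at least 4-fold different. The basal genes of the signature were higher by 0.21 and the luminal genes lower, at -0.30. These luminal genes came from control Sca1-positive cells and include Pgr, Foxa1 and Prom1, so the fall of hormone-sensing genes enters the score. Scores of Sca1-positive luminal cells were -2.47 ± 0.06 (SD, n = 2) in mutants and -2.39 ± 0.06 (SD, n = 3) in controls (exact permutation p = 0.3), a difference of -0.08 that turned to 0.007 after quantile normalization again and to 0.12 with the fixed lists. GFP-positive basal cells scored 0.71 ± 0.06 and GFP-negative basal cells 1.17 ± 0.32 (SD, n = 3 each), a difference of -0.45 (exact permutation p = 0.1, the smallest possible). GFP-negative replicate 2 scored 0.802, against 1.41 and 1.29 in replicates 1 and 3 and 0.655 to 0.782 in GFP-positive cells, and without it the difference was -0.64. With the fixed lists in place of the signatures the differences were 0.071 in Sca1-negative luminal and -0.74 in basal cells. The design cannot reach p under 0.05 for any of these scores.

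**Figure D4:**
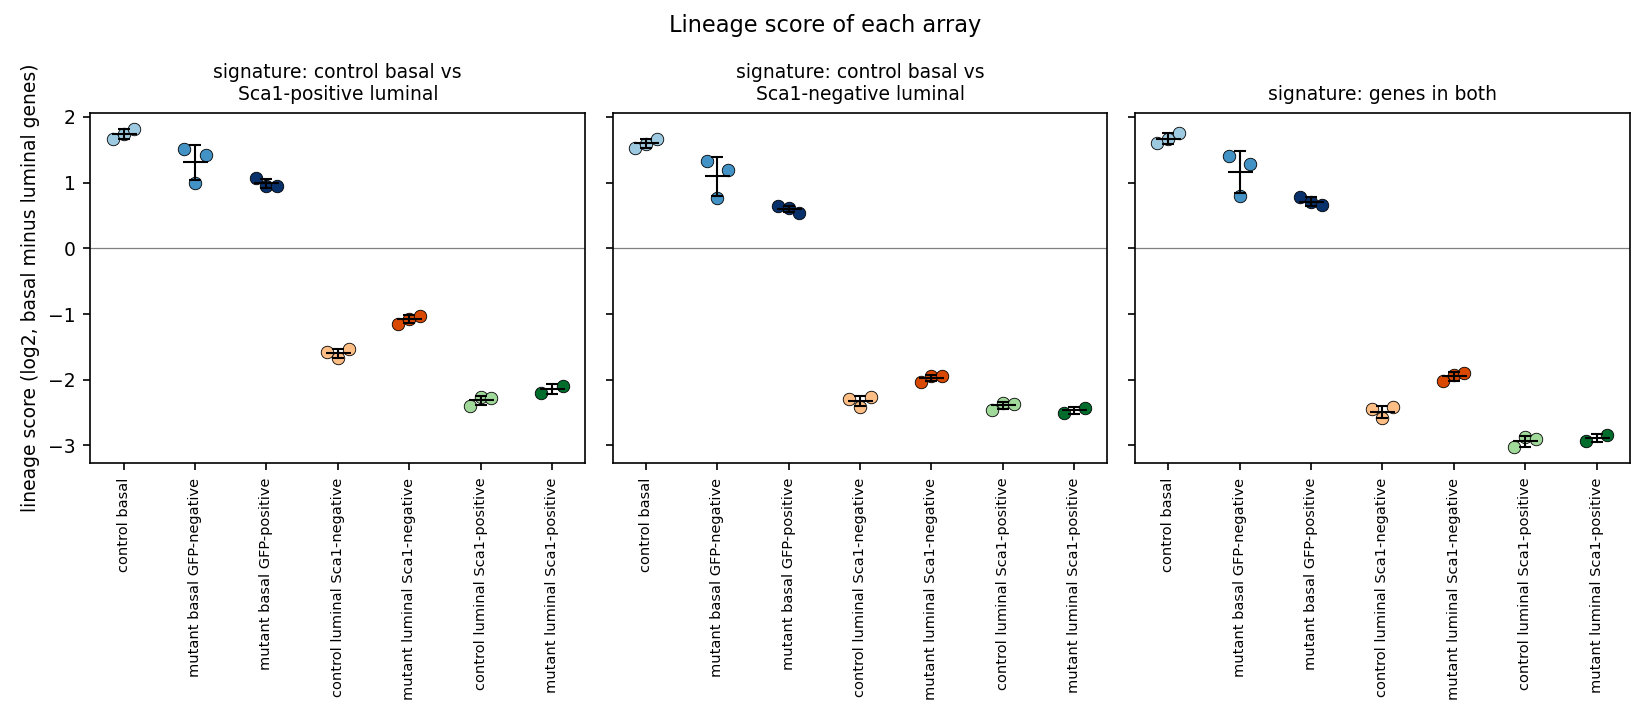
Lineage score (y axis, log2, mean of basal minus mean of luminal signature genes) of each array in the 7 groups (x axis) for 3 signatures taken from control cells; points are arrays, and bars show the mean and SD (n = 3, or 2 for mutant Sca1-positive luminal cells). In the signature from basal and Sca1-positive luminal controls, Sca1-negative luminal cells lie at -1.08 in mutants and -1.60 in controls.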

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

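The test on basal genes above both luminal subsets, the look at Gpx3, Amtn and Cxcl15, the test on GFP-negative cells and the neutrophil test were chosen only after the results they bear on were seen.

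The difference between mutant GFP-positive and control cells differed between lineages by the interaction test in 310 genes for basal against Sca1-negative luminal cells, 218 for basal against Sca1-positive luminal cells and 28 for Sca1-positive against Sca1-negative luminal cells. For basal against Sca1-negative luminal cells the log2 values were 5.97 (Dcn), 5.81 (Il33), 5.42 (Scrg1), 4.98 (Fndc1), 4.31 (Krt4), -4.79 (Amtn), -4.34 (Scn7a), -4.25 (Grik3), -3.95 (Ptprz1) and -3.74 (Lgr5). For basal against Sca1-positive luminal cells they were 5.40 (Scrg1), 5.22 (Il24), 5.08 (Fndc1), 4.63 (Sparcl1), 4.39 (Car12), -4.62 (Grik3), -4.24 (Scn7a), -4.14 (Chil1), -4.03 (Man1a) and -3.68 (Lgr5). Between the luminal subsets they were 3.16 (Tph1), 3.05 (Plac8), 2.97 (R3hdml), 2.82 (Krt4), 2.80 (Pwwp3b), -2.29 (Fyb2), -2.11 (Ogfrl1), -1.67 (Tmem37), -1.56 (Trpm6) and -1.51 (Smoc1). When genotype was regrouped at random within basal and within luminal arrays, apart from each other, 1 of 100 splits, the real one, gave 310 genes and the highest other gave 217. The gates were sorted from pools of mice that basal and luminal arrays can share, and 3 pools against 3 make 10 splits, too few for a share under 0.05.

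The 11799 probe sets without a listed gene were not used in the gene tests, and some showed a signal above the controls. With all probe sets tested, those called higher numbered 31 in Sca1-negative luminal, 7 in Sca1-positive luminal, 44 in GFP-positive basal and 1 in GFP-negative basal mutant cells against controls, and 35 in GFP-positive against GFP-negative basal cells. Those called lower numbered 16, 3, 76, 5 and 20 in the same order. Array control probe sets were not separated from the others.

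Of the 409 genes higher in GFP-positive than GFP-negative basal cells, 116 were also at least 2-fold higher in Sca1-negative luminal mutant cells than in GFP-negative basal cells, which luminal cells carried over into the basal gate could give. The 50 genes with the largest luminal excess imply a carried-over share of 9.76% (median, quartiles 4.69 and 16.2). The shared genes would need 49.6% (median, quartiles 31.6 and 90.5), and 25 of them lay at or above the luminal level. The shared genes were chosen as called higher in GFP-positive cells, which raises the share they need. The gap between these medians therefore decides nothing about carry-over. Of the 409 genes, 48.9% (200) were called higher than in both luminal mutant subsets. Luminal cells with the mean profile of those subsets cannot supply these genes. Luminal cells that differ from that profile were not measured and stay open. The same GFP-positive basal arrays were on the high side of each of these comparisons, which raises the percentage. Gpx3, Amtn and Cxcl15, abundant in the luminal cells, implied 0.305%, 0.807% and -0.597%. They were chosen after the results were seen and lie below the lower quartile of the 50 genes (4.69%). They therefore do not decide whether the share was near 10%. Shares were taken above GFP-negative cells, whose replicate 2 had a lineage score of 0.802, against 1.41 and 1.29 in the other replicates. That score lies nearer the luminal profile, which can lower the implied shares. A share near 10%, a smaller share, and luminal cells low in these genes all stay open. Whether any part of the difference is an effect of the mutant in basal-gate cells was not tested.

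Hormone-sensing genes were lower in Sca1-negative luminal mutant cells, which fewer hormone-sensing cells inside that gate could give. The 50 genes with the largest excess of control Sca1-positive over mutant Sca1-negative luminal cells were used. The share of such cells that the controls would need was 48.0% (median over the 50 genes, quartiles 40.5 and 64.0). The quartile ratio was 1.58, so the shares were alike, as a change in composition needs. The mutant arrays helped to choose these genes, which favours genes that are low in them. Of these 50 genes, 40 were called lower in Sca1-negative mutant cells, which the choice of genes favours. In Sca1-positive mutant cells, 3 were called lower and 0 higher. A like fall of all these genes within each cell would look the same, so lower expression caused by the mutant stays open and was not tested. Mutant cells were also chosen by GFP and control cells were not, and the part of that choice was not tested. The data are therefore consistent with a shift in composition without showing it.

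Serum amyloid and other genes were higher in all transgene-expressing subsets, which a difference between the animals, or neutrophils in the sorted cells, could give. For 16 genes higher in both luminal subsets, the median rise over control basal cells was 1.21 in GFP-positive and 0.157 in GFP-negative basal cells, or 13.03% of it (9 and 0 genes called). A difference that reaches GFP-negative and GFP-positive basal cells alike thus accounts for little of this median rise. The 0 called adds little, as 0.161% of all genes were called in GFP-negative basal cells. Single genes varied, and Saa1 and Saa2 were higher there by 1.35 and 1.19 without being called. Whether a part of their rise reaches cells without the transgene stays open. No GFP-negative luminal cells of the mutants were collected, so a difference between the animals that reaches luminal cells stays open. The 10 neutrophil genes had a median change of -0.046 in Sca1-negative luminal cells and -0.004 in GFP-positive against GFP-negative basal cells with 0 called higher, but they leave out S100a8, which was called higher, and their median level of 3.52 (S100a9 at most 3.72 in any group) is one that probe sets without response would also give. The test therefore decides nothing and neutrophils stay open, although sorting of CD45-negative cells would remove them. A factor from other cells that acts on transgene-expressing cells alone and a response of those cells to the mutant both stay open, and no test here separates them.

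Gene counts were set beside the other splits of the same 6 arrays. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 378 and 1 in Sca1-negative luminal cells, 843 and 6 in GFP-positive basal against control, 32 and 10 in GFP-negative basal against control, and 648 and 11 in GFP-positive against GFP-negative basal cells. They were 1972 and 2 for control basal against Sca1-negative luminal, 2445 and 0 against Sca1-positive luminal, 152 and 2 between the control luminal subsets, and 1911 and 1 for mutant basal against Sca1-negative luminal cells. For gene lists at the preset correlation they were 9 and 8 in Sca1-negative luminal, 10 and 11 in GFP-positive basal against control, 1 and 4 in GFP-negative basal against control, and 10 and 7 in GFP-positive against GFP-negative basal cells. The split with 11 lists set control basal replicates 1 and 3 with GFP-positive replicate 2, and 2 of the 10 splits gave at least 10 lists there. In GFP-negative basal against control, all 10 splits gave at least 1 list. Whether a structure among these arrays or too many calls at the preset correlation gave the splits with 4 lists was not tested.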

How the results depend on the processing

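The fit without both arrays of narrow spread (control Sca1-positive luminal replicate 2 and GFP-positive basal replicate 2) was chosen after seeing the data. Of 310 calls of named genes, 165 passed under every alternative run for genes. Of 41 list calls, 11 passed under those run for lists, which were the estimated correlation, the dim filter, quantile normalization again, median centring, the replicate block and the omission of arrays. None of these calls reversed. With only the compared arrays fitted, 181 of the 310 passed, and with all probe sets tested 270 did. Apart from the 2-fold limit, the cause was not tested.

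With only the compared arrays fitted, counts were 12 in Sca1-positive luminal, 276 in GFP-positive basal against control, 0 in GFP-negative basal against control (1362 at an unadjusted p under 0.05, limma), 134 in GFP-positive against GFP-negative basal, 43 between control luminal subsets and 124 for the basal to Sca1-positive interaction. They were 345 in Sca1-negative luminal cells and 946 between the mutant luminal subsets, so fewer arrays did not lower each count alike. Control and GFP-negative basal arrays had array weights of 0.677 to 0.933 and a mean r with their own group of 0.932 to 0.941. In Sca1-negative luminal arrays these were 1.19 to 1.75 and 0.954 to 0.970. These basal arrays thus spread more, so the spread pooled over 7 groups can be too small for basal comparisons and their counts too high. By how much was not tested. With array weights they were 819 in Sca1-negative luminal, 75 in Sca1-positive luminal, 10 in GFP-negative basal, 231 and 1493 between luminal subsets in controls and mutants, and 72 for the luminal interaction. A 2-fold limit, which removes small changes, gave 466 and 19 for GFP-positive and GFP-negative basal against control, 367 between them, 1277 and 1482 for control basal against Sca1-negative and Sca1-positive luminal, and 1173 for mutant basal against Sca1-negative luminal cells. Lists called fell to 11 with an estimated correlation. Scores with a 4-fold signature were 1.04 (Sca1-negative) and -0.14 (Sca1-positive). With the fixed lists they were 0.071 (Sca1-negative), 0.115 (Sca1-positive, reversed) and -0.741 (basal). Quantile normalization again gave 0.007 (Sca1-positive, reversed).

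Leaving out 1 array at a time, counts ran from 248 to 271 in Sca1-negative luminal (249 without control replicate 1, 248 without mutant replicate 3) and from 19 to 63 in Sca1-positive luminal (19 without mutant replicate 3). They ran from 630 to 760 in GFP-positive basal against control, 25 to 63 in GFP-negative basal (63 without its replicate 3) and 474 to 604 between them. Between luminal subsets they ran from 82 to 120 in controls (82 and 83 without Sca1-negative replicates 1 and 3) and 390 to 648 in mutants (460 and 390 without Sca1-positive replicates 1 and 3). For basal against luminal cells they ran from 1531 to 1796 (control, Sca1-negative), 1985 to 2149 (control, Sca1-positive), 1434 to 1767 (mutant, Sca1-negative) and 1322 to 1996 (mutant, Sca1-positive; 1341 and 1322 without Sca1-positive replicates 1 and 3). Interactions ran from 223 to 293 (basal, Sca1-negative), 117 to 216 (basal, Sca1-positive; 117 without mutant Sca1-positive replicate 3) and 20 to 46 (luminal; 45 and 46 without control or mutant Sca1-positive replicate 1). Lists ran from 37 to 46, and scores from 0.478 to 0.548, -0.117 to -0.037 and -0.636 to -0.331. Counts in 1 direction moved by over 1.5 times where the total did not. In Sca1-negative luminal cells, 152 were higher without control replicate 2, and 90 and 87 lower without mutant replicates 1 and 2. In Sca1-positive luminal cells, 23 were higher without control replicate 2, 59 higher and 4 lower without mutant replicate 1, and 5 lower after median centring. In GFP-negative basal cells, 21 were lower without control replicate 2 and 4 without GFP-negative replicate 2, and lower genes outnumbered higher ones without any 1 control array (18, 21 and 19 lower). Between control luminal subsets, 22 and 24 were higher without Sca1-negative replicate 2 and Sca1-positive replicate 3, and 74 lower without Sca1-positive replicate 2. Between mutant luminal subsets, 311 were higher without Sca1-negative replicate 3. In the luminal interaction, 10, 14 and 3 were lower without mutant Sca1-negative replicates 2 and 3 and Sca1-positive replicate 3. In the basal to Sca1-positive interaction, 66 were lower without control Sca1-positive replicate 2 and 73 higher without mutant Sca1-positive replicate 1. Without control basal replicate 1, the balance turned in both control basal contrasts (920 higher and 876 lower, and 1110 and 1039), and without replicate 2 in that with Sca1-positive luminal cells (1053 and 1012).

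Without 1 of the 2 mutant Sca1-positive arrays, the lone array was assumed to vary like the other groups.

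The labels do not state that replicate numbers mark paired samples. Over 57 pairs of arrays with the same number in different groups, r of the residuals had a median of 0.0189 and 5 pairs exceeded 0.1, while 15 of 20 arrays were on average closest to arrays of their own number, a hint from the data. With the replicate block, counts were 404, 40, 869, 29 and 645 in the 5 main comparisons, no count moved by over 1.5 times, and 15 of the 310 named calls and 2 of the 41 list calls ended. Without both narrow-spread arrays they were 412, 31, 760, 35 and 546. No scaling moved the median of all genes by 0.1 or more on the log2 scale. Signal over background limits dim genes, and a filter that left 14936 genes ended 1 of the 310 named calls and 3 of the 41 list calls.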

Other observations

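Compared with mutant Sca1-negative luminal cells, mutant GFP-positive basal cells had higher Myl9 (by 6.58), Vcan (6.06), Myh11 (5.71), Acta2 (smooth muscle actin, 5.66) and Emb (5.55), and lower Amtn (-5.75), the antioxidant enzyme gene Gpx3 (-5.17), Cxcl15 (-4.77), Ltf (-4.19) and Sprr1a (-4.14). Compared with mutant Sca1-positive luminal cells, Vcan (6.68), Myl9 (6.33), Acta2 (6.10), Postn (5.73) and Ecrg4 (5.68) were higher, and Gpx3 (-6.96), Cxcl15 (-6.71), Fam25c (-6.19), Ido1 (-6.02) and Wfdc2 (-5.96) were lower. In controls the widest differences between basal and Sca1-positive luminal cells were Myl9 (7.21), Acta2 (7.14), Postn (6.81), Cnn1 (6.78) and Sparc (6.63) on the basal side, and Gpx3 (-6.98), Krt4 (-6.35), Ly6d (-6.14), Cxcl15 (-6.02) and Tmprss2 (-5.66) on the luminal side. All of these calls by limma passed under every alternative set beforehand, and that of Sprr1a in the mutants ended without both arrays of narrow spread, an alternative added after the data were seen.

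The list tests on the interactions were added after the data were seen. Of 78 tests, 14 were called by camera with the preset correlation and 1 with an estimated correlation, that of hormone-sensing genes between the luminal subsets. Of 2 adjusted p given together, the second is that with an estimated correlation. Basal myoepithelial genes changed more negatively in basal than in Sca1-positive luminal cells (mean -0.78, adjusted p = 7.61e-07, and 0.074 with an estimated correlation) and than in Sca1-negative luminal cells (mean -0.50, adjusted p = 0.00432, and 0.277), and more positively in Sca1-positive than in Sca1-negative luminal cells (mean 0.28, adjusted p = 0.0382, and 0.414). Immediate early genes changed more negatively in basal than in Sca1-positive (mean -0.85, adjusted p = 1.21e-10, and 0.0886) and Sca1-negative luminal cells (mean -0.33, adjusted p = 0.0382, and 0.614), and more positively in Sca1-positive than in Sca1-negative luminal cells (mean 0.51, adjusted p = 4.89e-08, and 0.136). Luminal progenitor genes changed more positively in basal (mean 0.88, adjusted p = 0.000257, and 0.107) and in Sca1-positive luminal (mean 0.46, adjusted p = 0.0142, and 0.277) than in Sca1-negative luminal cells, and were not called between basal and Sca1-positive luminal cells (mean 0.42, adjusted p = 0.18). Hormone-sensing genes (mean 0.96, adjusted p = 0.000231, and 0.074) and luminal general genes (mean 0.61, adjusted p = 0.0288, and 0.614) changed more positively in basal than in Sca1-negative luminal cells. Hormone-sensing genes did not rise in basal cells. Their mean change against control was -0.395 in GFP-positive basal cells and -1.353 in Sca1-negative luminal cells. PI3K pathway components changed more positively in Sca1-positive than in Sca1-negative luminal cells (mean 0.31, adjusted p = 0.0406, and 0.258). The other 2 calls were of Wnt targets in the basal interactions.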
